A study of Mus musculus with 6 samples.

How the data were processed

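Bulk RNA sequencing of whole liver was analysed for 6 mice fed ethanol, 3 littermate controls and 3 mice in which a LysM-Cre allele deletes floxed Cd44 in myeloid cells. Per the labels' protocols, messenger RNA was selected with poly-T beads from DNase-treated total RNA, and the cDNA was primed with random hexamers. The deposited values were raw read counts per Ensembl gene, with 1 column per mouse, and no pooling of animals is stated in the labels. HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and the genome build GRCm38.p6 are named in the submitters' processing notes, without a role or an order. The strand setting, the treatment of reads that map to several places and the annotation release were not given in the sources used here. The Mup genes, and those of the largest changes that overlap an antisense gene, are therefore given as uncertain. Other genes with close copies carry the same limit without a mark at each value, and members of the gene lists are not marked for antisense overlap.

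Gene identifiers were matched to GENCODE M21 (GRCm38) for symbols, biotypes and coordinates, and 54495 of 54532 genes matched. Every column of counts was used. Library totals ran from 18428224 to 24042917 counts, so a limit of 3 counts corresponded to 0.12 to 0.15 CPM. Folds against a group with 0 counts in all libraries were computed against that limit of 3 counts in each library, which covers counting error only. Counts within a group differed by more than sampling noise in every pair of livers (chi-square per degree of freedom of at least 26.9), so no 2 libraries were counted as 1 sample. That each is a separate mouse is taken from the labels and was not tested.

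Genes were filtered by group with filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, without covariates. P-values were adjusted by the Benjamini-Hochberg method and a gene passed at an adjusted p under 0.05. Every adjusted p for a gene comes from this test unless another tool is named. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are counts scaled to the library total, with TMM-scaled library sizes. An exact permutation test of 3 livers against 3 cannot give a two-sided p below 0.1, so scores per liver carry that limit. Principal components were computed on log2 CPM with a prior count of 2 over the 500 most variable tested genes.

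The design, 38 gene lists with 497 symbols and the rule for named genes were fixed before the data were examined. Of these symbols, 1 (Ahsp) was not matched, and 36 lists had at least 4 tested members. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Camera with an estimated correlation and the rotation test fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. The named genes were Cd44 and Lyz2, together with the 12 largest log2 fold changes in each direction. The latter were chosen among protein-coding genes that passed the test, had a mean of at least 1 CPM and had groups that did not overlap. From each described list, up to 4 genes that passed were named by smallest p, or 2 with the smallest p where none passed. Some genes chosen by this rule are not reported here. A further gene is named where it completes a count of 5 or fewer, and those genes were chosen after their values were seen.

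The alternatives were DESeq2 1.42.0, limma-voom, relative log expression (RLE) size factors, scaling by library totals, no filter, and a filter of at least 50 counts in 3 libraries. They also included leaving out the 20 most abundant genes, protein-coding genes only, the mouse number as a block, other thresholds, and leaving out each library in turn. Offsets for GC content and gene length and scaling on the endothelial markers were added after seeing the data. Before use, the steps were tested on simulated counts made for this comparison, with 200 genes changed, 10 draws and 14438 to 14480 genes tested per draw. The test recovered 10.4% of genes changed 1.5-fold, 61.3% of those changed 2-fold and 95.9% of those changed 4-fold, and 7.4% of its calls were false. A simulated list of 12 raised genes passed the list test and 0 of 36 unchanged lists did. That list simulation was drawn once, with every gene drawn independently. It therefore does not show how often unchanged lists pass when their genes vary together, as in these livers (estimated correlation 0.846 for the shared myeloid markers). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.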

Results

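Livers were collected from mice on the C57BL/6J background after a model of alcohol-related liver injury. The mice drank a liquid diet with 6% ethanol by volume for 10 days, received 5 g of ethanol per kg by gavage on day 11, and were killed 9 hours later. Controls carried floxed Cd44 without Cre, and the knockout mice carried the same floxed gene with Cre inserted at Lyz2, the lysozyme gene of myeloid cells. Gene-level counts were obtained for 3 control and 3 knockout livers, and no livers of mice without ethanol were analysed here. Library totals were 23126828, 18428224 and 21621912 counts in the controls and 22227098, 24042917 and 21521174 counts in the knockouts. All CPM values below are means ± SD with n = 3 livers per group, and log2 values are the knockout against the control.

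CD44 is a cell-surface receptor for hyaluronan, and the comparison addressed how its loss from myeloid cells changes gene expression in the ethanol-exposed liver. The knockout mice also differ from the controls by Cre and the disrupted Lyz2 allele. No group with Cre alone was analysed here, so the effects of these cannot be told apart from those of Cd44 loss. Cd44 (ENSMUSG00000005087, chromosome 2, 102811141 to 102901665 on the minus strand, GRCm38) was 13.3-fold lower in the knockout livers. It stood at 32.6, 34.8 and 26.4 CPM in the 3 controls and at 2.11, 1.92 and 3.01 CPM in the 3 knockouts. The log2 fold change was −3.73 (SE 0.20, adjusted p = 9.07e-05). Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321 on the minus strand), which the Cre insertion disrupts, was 4.48-fold lower. Its levels were 195, 218 and 235 CPM in controls against 41.3, 36.9 and 66.5 CPM in knockouts (log2 −2.16, SE 0.22, adjusted p = 0.000756). Both genes were lower in every knockout liver than in any control, the direction that the genotype labels give. Lyz2 did not clearly fall by more than the monocyte and lipid-associated macrophage markers (given below), so its fall alone does not show the Cre insertion. Whole liver was sequenced, so the cells that lost Cd44 were not identified. Which Cd44 exons are floxed was not given in the sources used here, and the counts cover the whole gene.

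**Figure D1:**
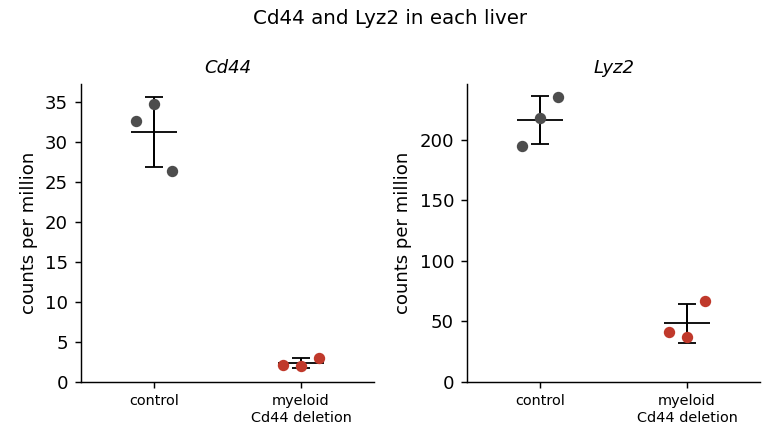
Cd44 (left) and Lyz2 (right) in CPM on linear axes that start at 0, with a point for each liver and the mean and SD of 3 livers per group as black bars. Knockout livers lay at 1.92 to 3.01 CPM for Cd44 and at 36.9 to 66.5 CPM for Lyz2, below all control livers.

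Of 14758 genes tested, 3684 (25%) passed the test, 1751 higher and 1933 lower in the knockout livers. Of these, 680 higher and 1154 lower genes changed by a log2 value of at least 1. The groups did not overlap for 6471 genes (43.8%), where chance gives 10%. The first principal component held 78.5% of the variance and placed the controls at −32.9 to −29 and the knockouts at 23.7 to 39. Scaling by library totals shifted the median of all genes by −0.25 on the log2 scale and gave 904 higher and 3698 lower genes. Without control liver 2 the count was 2275, and without knockout liver 1 it was 2296.

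The 12 genes named for the largest increases included 6 Mup genes. Major urinary proteins are lipocalins secreted by the liver, and Mup17, Mup18 and Mup16 had 0 counts in every control. They were at least 672-fold, 159-fold and 55.6-fold higher in the knockout livers, at 88.4 ± 79.99, 20.9 ± 13.1 and 7.32 ± 10.7 CPM. Knockout liver 2 carried much of these means (Mup16 stood at 1.678, 19.63 and 0.6407 CPM in the 3 knockouts), and without it the bounds were 337-fold, 101-fold and 8.81-fold. Mup22 (0.057 ± 0.067 to 239 ± 172 CPM), Mup2 (0.045 ± 0.044 to 3.19 ± 1.84 CPM) and Mup3 (18 ± 1.72 to 490 ± 249 CPM) rose too. These near-identical copies lie on chromosome 4 between 60135932 (the start of Mup2) and 62087342 (the end of Mup3), so the level of each is uncertain. Mup16 had an adjusted p of 0.0305, and 0.0688, 0.0695 and 0.0694 without control liver 1, 2 or 3 (range over 14 alternatives 2.52e-05 to 0.0695). The sulfotransferases Sult2a3 (0.115 ± 0.103 to 22.8 ± 7.58 CPM, adjusted p = 0.000179) and Sult3a1 (0.079 ± 0.102 to 12.1 ± 11.6 CPM, adjusted p = 0.00283) rose. The log2 change of Sult3a1 was 7.26, and 6.66, 8.85 and 6.11 without control liver 1, control liver 2 and knockout liver 2. That of Sult2a3 was 7.55, and 8.27 without control liver 1. Without control liver 3, Mup22 stood at 13.1 instead of 11.87 and Mup2 at 6.87 instead of 6.01, and Mup22 stood at 11.13 without knockout liver 2. Ces3b, a carboxylesterase, rose 17.3-fold (5.41 ± 0.894 to 93.9 ± 46.7 CPM) and Cyp3a16, a cytochrome P450, rose 18.3-fold (2.50 ± 1.77 to 46.0 ± 33.5 CPM), a log2 change of 4.2 that was 3.42 without knockout liver 1. Ptgds, a prostaglandin D synthase, rose 21.2-fold (0.174 ± 0.038 to 3.81 ± 1.28 CPM). Dct, a melanin-pathway enzyme, rose 20.2-fold (0.191 ± 0.13 to 3.93 ± 0.377 CPM). In the controls Mup22, Mup2, Sult2a3 and Sult3a1 averaged below the limit of 3 counts, and Ptgds and Dct lay close to it. The fold changes of these genes are fitted values that rest on few control counts.

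Among the largest decreases, the RNA-binding protein gene Rbm24 (chromosome 13, 46418434 to 46431095) fell from 8.73 ± 0.881 CPM to 0 counts in all 3 knockout livers, at least 60-fold lower. The epithelial keratin Krt20 fell 129-fold from 7.04 ± 5.09 CPM, and Slc7a11, the cystine transporter, fell 36.7-fold from 7.93 ± 3.25 to 0.211 ± 0.103 CPM. Vmn2r3 fell 102-fold from 13.8 ± 4.90 CPM, Insyn1 50.2-fold from 3.54 ± 1.39 CPM and Wfdc3 32.5-fold from 24.4 ± 6.93 CPM. Spire2, Syt14 and Lrtm2 fell 22.7-fold, 18.8-fold and 18.5-fold. In the knockouts Krt20, Insyn1 and Spire2 averaged 0.049, 0.065 and 0.082 CPM, below the limit of 3 counts. Vmn2r3 and Syt14 averaged 0.13 and 0.146 CPM, close to that limit. The folds of these genes are fitted values that rest on few counts, and are not comparable with the bound for Rbm24. The log2 change of Krt20 was −7.02, and −6.23 without control liver 2 and −7.88 without knockout liver 3. Also without knockout liver 3, Vmn2r3 stood at −8 instead of −6.67, Insyn1 at −6.89 instead of −5.65 and Spire2 at −6.04 instead of −4.5. Adam8, a leukocyte metalloprotease, fell 15.7-fold from 9.98 ± 2.47 CPM and Shc2 fell 19.5-fold from 13.7 ± 1.72 CPM. Adam8 overlaps the antisense gene Gm16201 and Shc2 overlaps Gm47163, and the strand setting of the counts was not given, so both are uncertain. Chil3, a product of alternatively activated macrophages and monocytes, fell from 9.93 ± 11.7 to 0.472 ± 0.379 CPM (adjusted p = 0.0151). Control liver 1 carried the control mean (23.43, 2.369 and 4.001 CPM in the 3 controls), and the log2 change of −4.39 was −2.74 without it and −5.21 without knockout liver 3. Its adjusted p was 0.0778 with limma-voom and 0.0575 without knockout liver 1 (range over 14 alternatives 2.01e-05 to 0.0778).

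Genes of myeloid cells fell together in the knockout livers. Of 18 markers shared by myeloid cells, 16 fell and 0 rose, and 17 fell when adjusted over the list alone (median log2 −1.28, camera adjusted p = 8.58e-11, adjusted p = 0.314 with an estimated correlation). The leukocyte tetraspanin Cd53 fell from 20.3 ± 3.31 to 7.12 ± 1.82 CPM and the integrin Itgb2 from 33.5 ± 4.48 to 12.2 ± 3.999 CPM. Laptm5 fell from 73.3 ± 5.63 to 27.8 ± 9.56 CPM and Spi1, the transcription factor PU.1, from 27.0 ± 1.75 to 10.4 ± 3.997 CPM. Of 10 markers of lipid-associated macrophages, 8 fell and 0 rose, 9 when adjusted over the list alone (median log2 −2.18, camera adjusted p = 2.33e-06, adjusted p = 0.314 with an estimated correlation). Gpnmb fell from 39.4 ± 7.25 to 2.83 ± 1.92 CPM, the tetraspanin Cd63 from 118 ± 11.4 to 25.9 ± 13.9 CPM, lipoprotein lipase Lpl from 212 ± 23.1 to 47.9 ± 30.5 CPM and galectin-3, Lgals3, from 57.9 ± 11.0 to 10.9 ± 8.26 CPM. Of 10 monocyte markers, 8 fell and 0 rose, 10 when adjusted over the list alone (median log2 −1.98, camera adjusted p = 3.96e-07, adjusted p = 0.269 with an estimated correlation). They included the chemokine receptor Cx3cr1 (5.65 ± 1.095 to 0.840 ± 0.064 CPM), Ms4a6c and Plac8, and 5 fell without knockout liver 1 and all 5 tested with the stricter filter.

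Of 12 markers of Kupffer cells, the resident macrophages of the liver, 8 fell and 1 rose, 9 and 1 when adjusted over the list alone (median log2 −0.87, camera adjusted p = 0.000746, adjusted p = 0.314 with an estimated correlation). The scavenger receptor Marco fell from 57.5 ± 20.4 to 14.8 ± 1.62 CPM, complement C6 from 36.9 ± 1.85 to 20.4 ± 3.53 CPM, Spic from 5.33 ± 1.43 to 2.10 ± 0.387 CPM and Adgre1, which encodes F4/80, from 52.2 ± 9.58 to 20.2 ± 9.74 CPM. Nr1h3, the nuclear receptor LXR-alpha, which hepatocytes also express, rose from 83.2 ± 6.48 to 114 ± 8.56 CPM. The Kupffer count was 4 without control liver 1, control liver 2 or knockout liver 1 and with endothelial scaling, and 5 without control liver 3. Nr1h3 did not pass without control liver 2, knockout liver 2 or knockout liver 3, with library totals or with the mouse number as a block. Of 10 neutrophil markers, 5 fell and 1 rose, 9 and 1 when adjusted over the list alone (median log2 −1.94, camera adjusted p = 0.0058, adjusted p = 0.468 with an estimated correlation). Csf3r fell from 8.20 ± 1.39 to 2.84 ± 1.21 CPM, S100a8 from 4.21 ± 2.00 to 0.763 ± 0.499 CPM and Mmp8 from 0.943 ± 0.497 to 0.162 ± 0.121 CPM, and S100a9 and Il1r2 fell too. Wfdc21, an acute-phase gene that hepatocytes can express, rose from 122 ± 20.2 to 370 ± 138 CPM. The neutrophil call was lost with the stricter filter (adjusted p = 0.252) and with fry (adjusted p = 0.07), and 2 markers fell without control liver 1 or knockout liver 1 or with the mouse-number block, 9 with library totals, 8 of 14 with no filter and 3 of 4 with the stricter filter.

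Markers of other cell types were examined in the same way. Of 8 dendritic cell markers, only Irf8 passed, falling from 17.2 ± 1.21 to 8.56 ± 2.35 CPM, 1 also when adjusted over the list alone (median log2 −0.88, camera adjusted p = 0.0371, adjusted p = 0.314 with an estimated correlation). That list call was lost with library totals (adjusted p = 0.108), without control liver 3 (adjusted p = 0.0505) and without knockout liver 2 (adjusted p = 0.0739), and 2 markers fell without control liver 1, knockout liver 1 or knockout liver 3 or with no filter, 3 with library totals and 0 with endothelial scaling. Of 16 T and NK cell markers only 9 passed the count filter, and of these Ccl5 alone fell (4.33 ± 0.775 to 1.17 ± 0.626 CPM). Of 10 B and plasma cell markers only 6 passed the filter, and of these Cd22 alone fell (3.58 ± 0.305 to 1.604 ± 0.551 CPM). Both counts of falling markers were the same when adjusted over the list alone, and neither list passed the list test (camera adjusted p = 0.221 and 0.585). Without knockout liver 3 the T and NK list had an adjusted p of 0.0498 and 2 markers fell, and Cd22 did not pass without control liver 1, control liver 2 or knockout liver 1 or with endothelial scaling. With library totals 3 T and NK markers and 2 B and plasma markers fell. Of 11 endothelial markers, 0 passed by edgeR, also when adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 1 (camera adjusted p = 0.649). With library totals 4 of the 11 fell, with the mouse number as a block 2, and with no filter or with endothelial scaling 1. Without knockout liver 2, 2 of them fell, and the smallest p belonged to Lyve1 (49.4 ± 8.25 against 23.3 ± 14.5 CPM) and Cdh5 (36.2 ± 6.68 against 26.7 ± 3.66 CPM). Of 9 stellate cell markers, Pdgfrb (26.3 ± 1.19 to 14.95 ± 2.05 CPM) and Des (10.4 ± 0.192 to 6.56 ± 0.869 CPM) fell and Ecm1 rose (139 ± 25.7 to 224 ± 20.6 CPM), also when adjusted over the list alone (camera adjusted p = 0.553), and 1 fell without control liver 2 or 3 or with endothelial scaling. With library totals 4 stellate markers fell and 0 rose, and with the GC and length offsets 2 rose. Of 7 cholangiocyte markers, 0 passed by edgeR, also when adjusted over the list alone, or by DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.585). Without knockout liver 2, or with library totals, 1 of them fell. Over all livers Krt19 stood at 1.43 ± 0.104 against 0.841 ± 0.087 CPM and Sox9 at 10.9 ± 3.02 against 5.87 ± 4.17 CPM. All 5 tested erythroid genes rose, also when adjusted over the list alone (median log2 1.14, camera adjusted p = 0.000812, adjusted p = 0.314 with an estimated correlation). Hba-a1 rose from 23.0 ± 7.91 to 55.5 ± 8.24 CPM, Hbb-bs from 32.3 ± 10.6 to 71.1 ± 7.29 CPM and Alas2, the heme synthesis enzyme of red cell precursors, from 4.33 ± 0.755 to 8.57 ± 1.15 CPM. Hba-a2 and Hbb-bt, near-identical copies of the globin genes, rose as well, and 3 of the 5 passed without control liver 3 or knockout liver 1. How the globin rise is divided among these copies is uncertain.

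Of 12 hepatocyte markers, 3 rose and 0 fell, 3 also when adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.497 with an estimated correlation). Ttr, the thyroxine carrier, rose from 1695 ± 249 to 3953 ± 435 CPM, the antitrypsin gene Serpina1c from 274 ± 91.7 to 618 ± 200 CPM and the urea cycle enzyme Cps1 from 3339 ± 1226 to 7226 ± 2037 CPM. The list median was 0.23 and turned to −0.03 with library totals. The call was lost with the stricter filter (adjusted p = 0.058), with fry (0.0616), without control liver 1 (0.0606) and without knockout liver 2 (0.0739), and 1 marker passed without control liver 1 and 5 without knockout liver 3, with no filter or with endothelial scaling. Albumin took 6.25% ± 0.45 of all counts in controls and 7.64% ± 0.77 in knockouts. Too few markers were tested for a list test in pancreatic acinar cells (Cela1, 7.29 ± 0.880 against 7.37 ± 0.803 CPM) and adipocytes. Of the latter, Car3 rose from 44.0 ± 29.9 to 471 ± 80.9 CPM and Fabp4 fell from 26.4 ± 4.50 to 11.2 ± 4.58 CPM.

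Inflammatory and matrix genes were lower in the knockout livers. Of 20 chemokine, cytokine and adhesion genes, 16 fell and 0 rose, 18 when adjusted over the list alone (median log2 −1.61, camera adjusted p = 1.31e-12, adjusted p = 0.0358 with an estimated correlation). The endotoxin co-receptor Cd14 fell from 65.8 ± 27.0 to 10.1 ± 1.74 CPM, the adhesion molecule Icam1 from 58.4 ± 9.10 to 27.2 ± 1.85 CPM, the interleukin-1 receptor antagonist Il1rn from 44.5 ± 12.3 to 12.9 ± 2.47 CPM and the neutrophil chemokine Cxcl1 from 30.7 ± 6.09 to 3.84 ± 2.46 CPM. Of 18 extracellular matrix and fibrosis genes, 17 fell and 0 rose, also when adjusted over the list alone (median log2 −1.66, camera adjusted p = 9.92e-16, adjusted p = 0.0462 with an estimated correlation). The collagens Col5a2 (16.2 ± 0.853 to 4.22 ± 0.854 CPM), Col4a1 (212 ± 24.1 to 76.8 ± 9.69 CPM) and Col6a1 (27.8 ± 2.35 to 12.7 ± 1.49 CPM) fell with the intermediate filament gene Vim (55.4 ± 7.27 to 18.7 ± 2.30 CPM). Of 18 interferon-stimulated genes, 8 fell and 0 rose, 9 when adjusted over the list alone (median log2 −0.60, camera adjusted p = 0.000746, adjusted p = 0.517 with an estimated correlation). Rsad2, the antiviral enzyme viperin, fell from 75.2 ± 2.38 to 16.3 ± 5.78 CPM, and Cmpk2, Oas1a and Ifit2 fell too. The interferon call was lost with fry (adjusted p = 0.0841), and the count was 4 without control liver 1 or 2, 3 without control liver 3 or with endothelial scaling and 5 without knockout liver 3, and 1 rose without knockout liver 2.

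Acute-phase genes went both ways, with 3 of 17 higher and 3 lower, 3 and 4 when adjusted over the list alone (camera adjusted p = 0.814). Hepcidin, Hamp, fell from 736 ± 499 to 59.5 ± 24.4 CPM, lipocalin-2, Lcn2, from 1213 ± 323 to 225 ± 141 CPM and Steap4 from 377 ± 178 to 137 ± 25.7 CPM. C-reactive protein, Crp, rose from 268 ± 65.8 to 518 ± 21.6 CPM, and Orm3 (6.28 ± 4.47 to 25.1 ± 11.0 CPM) and Itih4 (2156 ± 457 to 3710 ± 892 CPM) rose. Without control liver 2 or 3, 1 acute-phase gene rose. Of 7 genes of MHC class II presentation, H2-DMb1 fell (9.97 ± 1.54 to 4.20 ± 2.46 CPM), 0 when adjusted over the list alone. The list stood at a camera adjusted p of 0.0509 and passed in other settings, such as RLE factors (0.0491), no filter (0.00903) and without knockout liver 3 (0.000727). All 7 fell without knockout liver 3, and 0 passed without any 1 of the controls, without knockout liver 1 or with endothelial scaling, while 2 fell with library totals and 4 with no filter. Of 10 hyaluronan and CD44 partner genes, the membrane-cytoskeleton linkers Msn (60.9 ± 6.88 to 29.7 ± 3.35 CPM) and Ezr (14.4 ± 2.03 to 9.54 ± 1.16 CPM) fell and 0 rose, 2 also when adjusted over the list alone (camera adjusted p = 0.229). That list had an adjusted p of 0.0465 with fry and 0.045 without knockout liver 2, and 1 gene fell without control liver 2 or knockout liver 1 or 3 and 4 without knockout liver 2, with library totals, with the mouse-number block or with no filter.

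**Figure D2:**
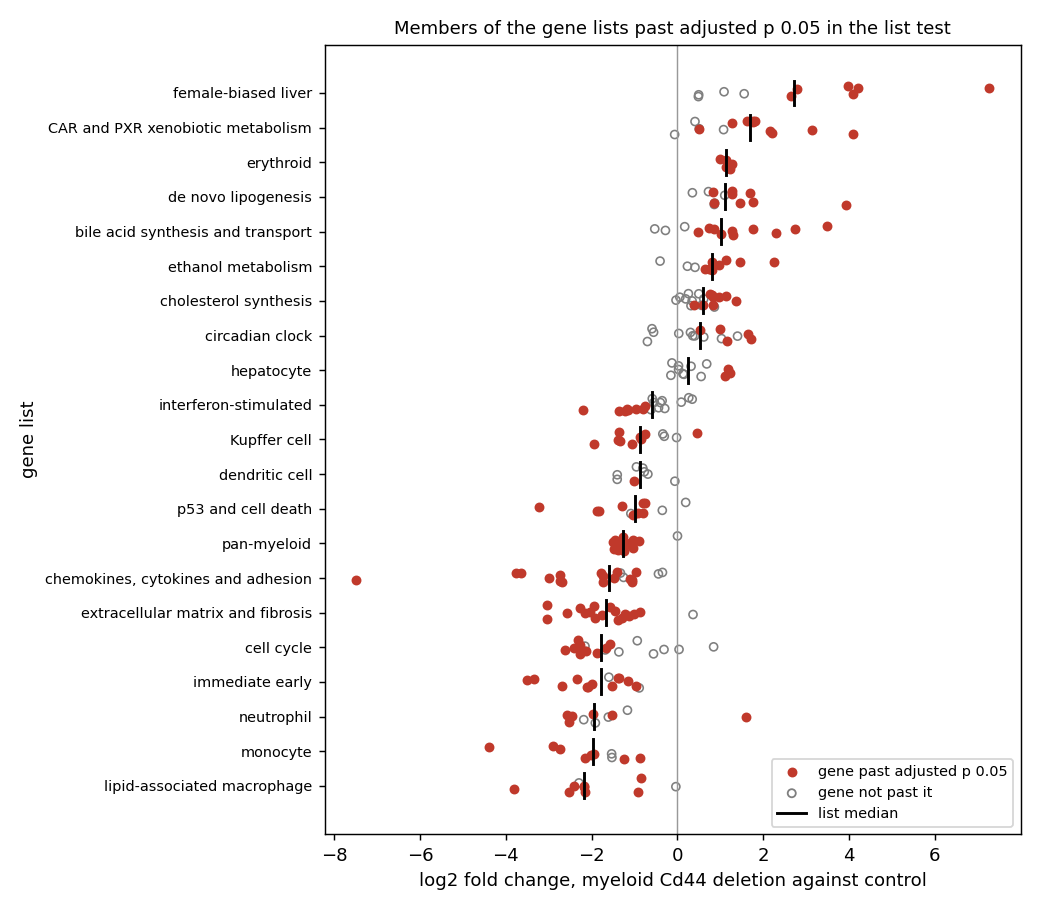
Log2 fold change of each tested member (horizontal axis) of the 21 gene lists that passed the list test (vertical axis, sorted by median), with filled points for genes that passed and open points for genes that did not. The black bar is the list median, which ran from −2.18 for lipid-associated macrophages to 2.72 for female-biased liver genes, and genes with 0 counts in a group are drawn at fitted values.

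Genes of bile acid, ethanol and drug metabolism rose. Of 13 bile acid genes, 10 rose and 0 fell, also when adjusted over the list alone (median log2 1.02, camera adjusted p = 3.01e-08, adjusted p = 0.0396 with an estimated correlation). Cyp8b1, the sterol 12-alpha-hydroxylase, rose from 15.7 ± 4.04 to 175 ± 46.7 CPM, and Slc10a1, the bile acid importer NTCP, from 187 ± 55.7 to 926 ± 160 CPM. Nr1h4, the bile acid receptor FXR, rose from 71.4 ± 14.1 to 171 ± 14.4 CPM, and the importer Slco1b2 from 283 ± 98.1 to 954 ± 184 CPM. Of 14 genes of drug metabolism under the receptors CAR and PXR, 10 rose and 0 fell, also when adjusted over the list alone (median log2 1.69, camera adjusted p = 3.22e-12, adjusted p = 0.152 with an estimated correlation). Cyp2b13 rose from 16.9 ± 4.08 to 288 ± 94.1 CPM, Cyp2c37 from 113 ± 27.1 to 988 ± 165 CPM, Nr1i3, which encodes CAR, from 13.6 ± 2.69 to 60.6 ± 9.96 CPM and the bilirubin conjugating enzyme Ugt1a1 from 76.0 ± 6.79 to 182 ± 20.1 CPM. Of 11 ethanol metabolism genes, 8 rose and 0 fell, and 8 rose and 1 (Aldh1b1, 224 ± 36.8 against 169 ± 19.9 CPM) fell when adjusted over the list alone. Over all genes, 1 fell with library totals or without control liver 1. The list median was 0.80 (camera adjusted p = 1.09e-05, adjusted p = 0.163 with an estimated correlation). The acetate-activating enzyme Acss2 rose from 31.5 ± 5.80 to 87.0 ± 13.4 CPM, catalase, Cat, from 864 ± 49.3 to 1677 ± 37.7 CPM, Cyp2e1, the inducible ethanol oxidase, from 928 ± 316 to 4427 ± 1667 CPM and Adh5 from 164 ± 11.8 to 271 ± 13.4 CPM.

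Lipid synthesis genes rose in part. Of 13 lipogenic genes, 8 rose and 0 fell, 11 when adjusted over the list alone (median log2 1.1, camera adjusted p = 5.17e-08, adjusted p = 0.223 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, rose from 58.2 ± 15.6 to 188 ± 18.3 CPM, malic enzyme Me1 from 102 ± 17.5 to 245 ± 20.6 CPM, Mlxipl, which encodes ChREBP, from 79.9 ± 10.1 to 192 ± 29.7 CPM and the lipogenic regulator Thrsp from 23.6 ± 15.5 to 360 ± 147 CPM. Of 19 cholesterol synthesis genes, 9 rose and 0 fell, 12 when adjusted over the list alone (median log2 0.59, camera adjusted p = 5.52e-05, adjusted p = 0.4 with an estimated correlation, 0.0527 with fry). Stard4 (36.0 ± 10.7 to 93.2 ± 12.4 CPM), Idi1 (15.6 ± 2.09 to 34.0 ± 7.88 CPM), Nsdhl and Cyp51 rose. Of 11 lipid droplet and uptake genes, 4 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.118). The droplet proteins Cidec (122 ± 42.4 to 31.8 ± 9.43 CPM) and Plin2 (1141 ± 283 to 704 ± 40.4 CPM) fell with Hilpda (15.4 ± 3.49 to 4.16 ± 0.573 CPM) and Fabp4. The droplet list passed with no filter (0.0203), fry (0.0302) and without control liver 3 (0.0331), where its median turned to 0.004, and 1 gene rose without control liver 1, knockout liver 2 or knockout liver 3 and 2 with no filter. Of 17 fatty acid oxidation and PPAR-alpha target genes, 3 rose and 3 fell, 4 and 3 when adjusted over the list alone (camera adjusted p = 0.596). Cyp4a31 (67.9 ± 11.98 to 8.48 ± 0.142 CPM), Pdk4 (73.6 ± 50.1 to 12.7 ± 0.839 CPM) and Ehhadh fell, and Ppara (62.5 ± 7.05 to 119 ± 29.7 CPM), Vnn1 and Creb3l3 rose. Without control liver 1, 5 genes of this list rose, and without control liver 2, 1 did. Of 14 gluconeogenesis and fasting genes, 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.229). G6pc (121 ± 14.5 to 416 ± 53.6 CPM), Fbp1 (631 ± 162 to 1511 ± 156 CPM), Pklr (69.1 ± 25.7 to 375 ± 175 CPM) and Slc2a2 rose, and Igfbp1 fell (1759 ± 405 to 449 ± 109 CPM). Without knockout liver 3, with the mouse-number block or with no filter, 2 genes of this list fell.

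Genes of early transcription, the p53 response and the cell cycle fell. Of 14 immediate early genes, 12 fell and 0 rose, 14 when adjusted over the list alone (median log2 −1.79, camera adjusted p = 1.81e-13, adjusted p = 0.0408 with an estimated correlation). Ccn1 fell from 39.7 ± 1.91 to 9.22 ± 1.62 CPM, Klf6 from 115 ± 10.4 to 29.1 ± 6.26 CPM, Btg2 from 200 ± 52.2 to 30.7 ± 6.73 CPM and Ier3 from 33.7 ± 20.6 to 2.95 ± 1.19 CPM. Of 12 p53 and cell death genes, 9 fell and 0 rose, 10 when adjusted over the list alone (median log2 −0.98, camera adjusted p = 4.97e-09, adjusted p = 0.0358 with an estimated correlation). The p53 targets Phlda3 (28.5 ± 1.52 to 3.06 ± 1.04 CPM), Ccng1 (112 ± 8.54 to 54.3 ± 6.63 CPM) and Trp53inp1 (634 ± 128 to 174 ± 48.0 CPM) fell with Gadd45b (12.97 ± 1.35 to 5.26 ± 0.238 CPM). Of 18 cell cycle genes, 9 fell and 0 rose, 10 when adjusted over the list alone (median log2 −1.78, camera adjusted p = 0.000746, adjusted p = 0.498 with an estimated correlation, 0.119 with fry). They included cyclin E1, Ccne1 (6.08 ± 0.901 to 1.92 ± 0.466 CPM), Cdk1 (5.51 ± 3.06 to 1.13 ± 0.337 CPM) and the replication helicase genes Mcm6 and Mcm5. The cell cycle count was 4, 2, 3 and 5 without control liver 2, control liver 3, knockout liver 1 and knockout liver 2, and 13 of 19 tested without control liver 1 and 14 of 19 with no filter.

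**Figure D3:**
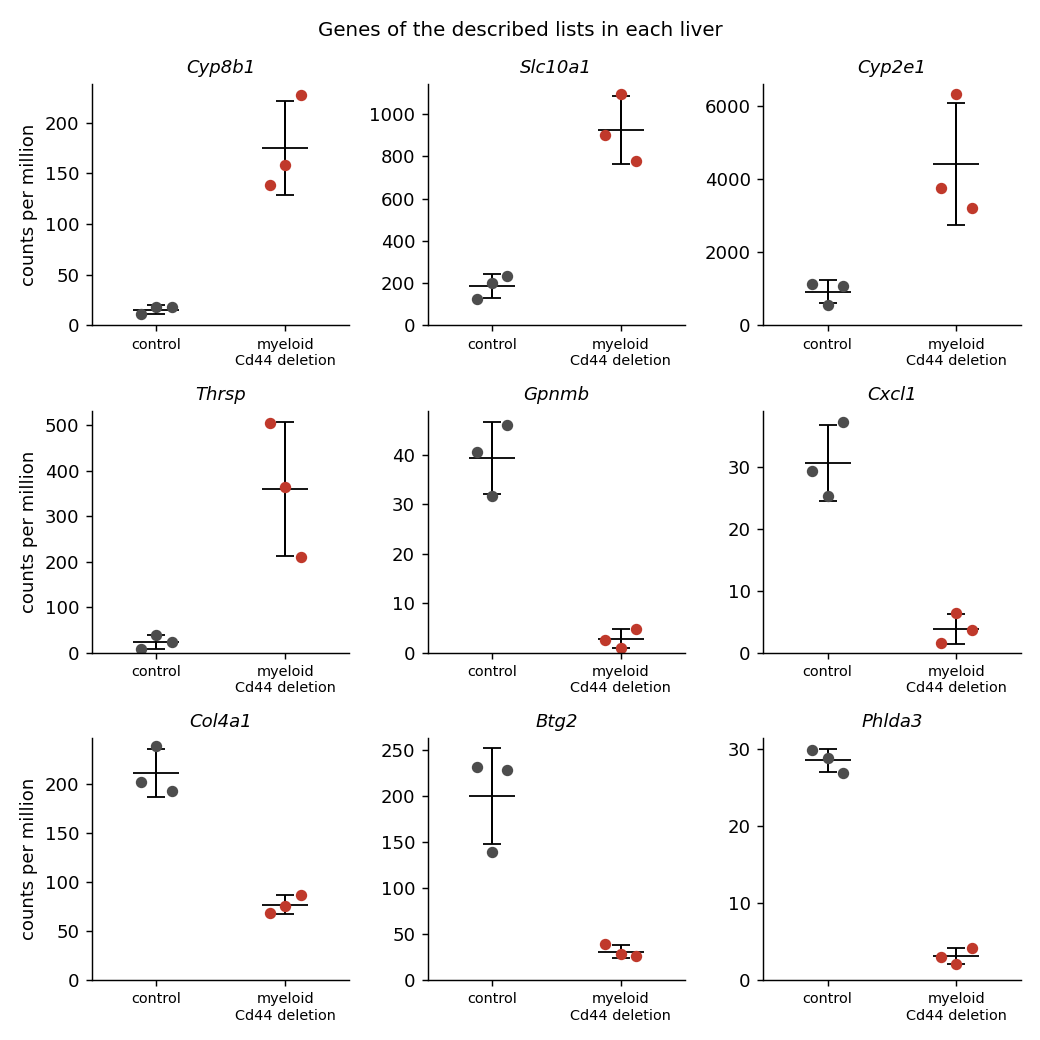
CPM on linear axes that start at 0 for 9 genes, with a point for each liver and the mean and SD of 3 livers per group as black bars. Cyp8b1, Slc10a1, Cyp2e1 and Thrsp were higher and Gpnmb, Cxcl1, Col4a1, Btg2 and Phlda3 lower in all 3 knockout livers than in any control.

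Sex-biased, clock and stress genes completed the lists. Of 10 female-biased liver genes, 6 rose and 0 fell, 9 when adjusted over the list alone (median log2 2.72, camera adjusted p = 6.09e-10, adjusted p = 0.0358 with an estimated correlation). Hao2 rose from 3.53 ± 1.96 to 24.3 ± 8.48 CPM, alongside Cyp2b13 and Sult3a1. Of 13 male-biased genes only 4 were tested. Among these Cyp7b1 rose (4.06 ± 0.804 to 10.0 ± 1.98 CPM), 1 also when adjusted over the list alone (camera adjusted p = 0.413), and 2 did without knockout liver 3 or with no filter. Whether the groups held mice of the same sex was not tested. Of 15 circadian clock genes, 5 rose and 0 fell, also when adjusted over the list alone (median log2 0.52, camera adjusted p = 0.00854, adjusted p = 0.4 with an estimated correlation). Hlf (17.8 ± 6.53 to 58.7 ± 11.4 CPM), Per2 (19.7 ± 3.51 to 43.5 ± 9.02 CPM), Tef, Per3 and Cry2 rose, and the list call was lost without knockout liver 2 (adjusted p = 0.0513), where 1 gene fell. Of 15 NRF2 and glutathione genes, Gclm rose (180 ± 14.2 to 272 ± 10.2 CPM) and Slc7a11 fell, also when adjusted over the list alone (camera adjusted p = 0.553). Without control liver 2, 2 genes of this list rose, and with library totals 0 did. In it 2 fell without control liver 1 or knockout liver 2, with library totals, the mouse-number block or the GC and length offsets, and 3 without knockout liver 3 or with no filter. Of 15 ER stress genes, Asns, asparagine synthetase, fell (21.7 ± 5.40 to 7.66 ± 4.57 CPM), 0 when adjusted over the list alone (camera adjusted p = 0.146). That list passed without control liver 2 (0.028) and without knockout liver 1 (0.0117), and 0 genes fell without control liver 1, 2 without knockout liver 1 or 2 or with the mouse-number block, 3 with no filter and 5 with library totals. Of 13 mitochondrially encoded genes, mt-Nd1 rose (4180 ± 146 to 6019 ± 145 CPM), 0 when adjusted over the list alone (camera adjusted p = 0.0623). The mitochondrial list passed with no filter (0.0144), fry (0.0304), without control liver 1 (0.0474) and without knockout liver 3 (0.0368), and 2 genes rose without control liver 1, with no filter or with endothelial scaling and 0 without control liver 2 or 3 or knockout liver 1 or 2. With the mouse-number block or the GC and length offsets 0 rose, as did 0 of the 9 tested when the 20 most abundant genes were left out, and with library totals 0 rose and 1 fell.

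Of the 36 lists, 21 passed, 9 higher and 12 lower. With an estimated correlation 6 held, namely chemokines and adhesion, extracellular matrix, bile acids, p53, immediate early genes and female-biased genes. With fry, 19 of the 36 lists passed.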

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

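Offsets for GC content and gene length and scaling on endothelial markers were chosen after seeing the data, and the other alternatives were fixed before. No gene that passed changed sign under any alternative fit. DESeq2 gave 3968 genes, limma-voom 3778, RLE factors 3711, and the offsets 3727, and 94.9%, 97.3%, 99.6% and 94.5% of the 3684 genes passed there too. Library totals gave 904 higher and 3698 lower genes, and endothelial scaling gave 1930 higher and 1039 lower genes and shifted the median gene by 0.18 on the log2 scale. The direction of the split therefore depends on the scaling. Requiring a log2 change of at least 1 left 1834 genes. Leaving out each library in turn gave 2275 to 3413 genes, 1086 to 1576 higher and 1183 to 1837 lower, with fewer livers in each fit. Cd44 stayed between −3.99 and −3.55 and Lyz2 between −2.46 and −1.95, past the threshold in all 17 alternatives. The lists that passed fell from 21 to 6 with an estimated correlation, and numbered 18 to 24 in the other alternatives. The first principal component held 65.9% of the variance over all tested genes, against 78.5% for 500 genes. The mouse numbers in the titles, which differ in part from those of the count columns, gave no sign of pairing. Same-numbered livers deviated together with r = −0.027, 0.044 and −0.018, and not every liver correlated best with its own number. With 3 livers per group these values cannot exclude a pairing or a batch. A block for the title numbers gave 3086 genes. With 3 livers per group, changes below 2-fold were often missed in the simulated counts, 10.4% of those of 1.5-fold being recovered. Only 200 genes were changed there, against 3684 that passed here, so the recovery in these livers may differ.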

Other observations

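The gene groups in this and the next paragraph were chosen after the data had been seen, so their counts describe the genes chosen, are no independent evidence of a direction, and their list tests are not given. Of 12 pericentral hepatocyte genes, 8 rose and 0 fell (median log2 1.72). The glutamate transporter Slc1a2 rose from 15.01 ± 6.90 to 106 ± 18.2 CPM (n = 3 per group throughout), glutamine synthetase, Glul, from 251 ± 91.1 to 1164 ± 157 CPM and Oat from 260 ± 111 to 998 ± 131 CPM. Of 12 periportal genes, 5 rose, 1 fell and 6 did not pass. Cyp2f2 rose from 219 ± 32.6 to 784 ± 82.6 CPM and Hal from 147 ± 14.7 to 425 ± 96.5 CPM, while the epithelial cadherin Cdh1 fell from 91.6 ± 22.5 to 41.8 ± 9.21 CPM. Of 10 growth hormone axis genes, 5 rose and 0 fell, among them Igfals (31.9 ± 2.71 to 117 ± 11.9 CPM), the receptor Ghr (120 ± 18.1 to 319 ± 24.6 CPM) and Igf1 (259 ± 34.0 to 478 ± 51.9 CPM).

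Of 16 complement and coagulation genes, 12 rose and 0 fell, including F7 (51.2 ± 4.80 to 132 ± 19.1 CPM) and F11 (25.7 ± 2.58 to 53.4 ± 5.08 CPM). Of 14 cytoskeleton and epithelial injury genes, 12 fell and 0 rose (median log2 −1.46). The urokinase receptor Plaur fell from 11.4 ± 3.33 to 1.72 ± 0.400 CPM, S100a6 from 6.60 ± 2.34 to 0.873 ± 0.110 CPM and Tmsb10 from 50.3 ± 7.65 to 9.23 ± 3.77 CPM. Of 11 genes of fetal or dedifferentiated hepatocytes, 6 fell and 0 rose, among them Tnfrsf12a (143 ± 37.7 to 38.0 ± 11.5 CPM) and the imprinted RNA H19 (9.92 ± 6.89 to 1.08 ± 0.823 CPM).

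The tests below were chosen after the gene and list results had been seen, the split count and the marker scores included. The 6 livers can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3684 genes, the highest other split gave 1, and the real split was the only 1 of the 10 with that many. With offsets for GC content and gene length 3727 genes passed, so that bias did not account for the count.

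Cd44 fell by more than the means of the 5 myeloid marker sets compared here, and Lyz2 by more than only some of them. Cd44 minus the mean of the shared myeloid markers was lower in the knockouts by a log2 difference of −2.44 (SE 0.18, exact permutation p = 0.1, the smallest possible). In scores computed later the difference was −1.75 (SE 0.39) against monocyte, −1.51 (SE 0.43) against lipid-associated macrophage, −2.17 (SE 0.50) against neutrophil and −2.86 (SE 0.11) against Kupffer cell markers. Cd44 thus fell beyond the average marker of each set. The set means include members that did not fall, and Gpnmb alone fell as far (log2 −3.80, against −3.73 for Cd44). Fewer myeloid cells alone are therefore not excluded for Cd44. For Lyz2 the difference was −0.95 (SE 0.19) against the shared and −1.37 (SE 0.18) against the Kupffer cell markers, but −0.26 (SE 0.42) against monocyte, −0.01 (SE 0.37) against lipid-associated macrophage and −0.67 (SE 0.55) against neutrophil markers. Fewer cells of those types, the loss of 1 of 2 alleles to the Cre insertion, which would give −1, and lower activity in the remaining cells therefore stay open for Lyz2.

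Myeloid markers fell while hepatocyte metabolic genes rose, and a shift in cell shares may account for either. A lower share of all cells other than hepatocytes would lower their markers alike, but the myeloid mean minus the endothelial mean fell by 1.08 on the log2 scale (SE 0.45, exact permutation p = 0.1, the smallest possible). That is only 2.41 SE with 3 livers per group, and knockout liver 3 at 0.27 came close to the lowest control at 0.57. A lower share of all cells other than hepatocytes is therefore not excluded. Scores computed after that value were −1.12 (SE 0.34) against stellate markers and −1.03 (SE 0.43) against the mean of endothelial, stellate and cholangiocyte markers. A higher share of hepatocytes alone would not raise bile acid genes over other hepatocyte genes, yet their difference rose by 0.80 (SE 0.08). The bile acid genes were chosen after their rise had been seen, so this score cannot decide against a higher hepatocyte share. The fatty acid oxidation and gluconeogenesis lists had medians of 0.03 and −0.04, against 0.23 for the hepatocyte markers. A higher hepatocyte share, fewer myeloid cells, lower transcription per myeloid cell and an altered hepatocyte state stay open as hypotheses.

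With a mean of at least 1 CPM, 34 genes changed by a log2 value of at least 4, 11 lower and 23 higher, 6 of them Mup genes and 3 Mup pseudogenes. Both groups carry the floxed Cd44 gene, so passenger DNA could differ only around the Cre insertion at Lyz2. It would place these genes near Lyz2, but 0 of the 34 lay within 10 Mb of Lyz2 or of Cd44. Over both windows together, 23.6% of 161 genes passed against 25% elsewhere (Fisher's exact p = 0.78). That share pools the Cd44 window with the Lyz2 window, so it does not decide the question for Lyz2. Reads moved between near-identical Mup copies would leave the family sum level only if every such read were counted within it. The sum over the Mup genes rose from 54.7 ± 16.3 to 885 ± 516 CPM (log2 difference 3.90, SE 0.53, exact permutation p = 0.1, the smallest possible). It leaves out the Mup pseudogenes, and the treatment of reads that map to several places was not given. Moved or dropped reads are therefore not excluded. How the rise is divided among the Mup copies stays open, as does a strain difference elsewhere in the genome. A higher output of the Mup family in the knockout livers remains a hypothesis in line with the genotype, found and tested on the same data.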
